A study of Mus musculus with 2 samples.

How the data were processed

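Gene expression was measured by Illumina bead array in Flt3-low LSK cells of mice, with 1 control sample and 1 sample of the genotype written CA/CA in the labels. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy micro kit, checked on an Agilent Bioanalyser, amplified and biotin-labelled with an Illumina kit and hybridised in 1 colour. The submitters' processing notes name BeadStudio. Its version, normalization method and settings are not given in the sources used here.

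The values analysed were the authors' deposited intensity values of 45281 probes per array, one column per sample and headed with the sample's own identifier. Their scale was worked out from the values. They were linear, ran from 71.85 to 17158.7 and had the same median of 86.15 on both arrays, with no centring of genes. The sorted columns differed by at most 0.0022 on the log2 scale, as after quantile normalization between arrays. Most probes lay close to a common background that had not been subtracted. A second table of non-normalized signals and detection p-values held 4 value columns whose headings matched no sample label. Columns were assigned by heading only, never by their values, so these 4 columns stayed unassigned and no value given here comes from them. The design fixed beforehand had foreseen background correction from that table, so its stated fallback, log2 of the normalized signal plus 16, became the main scale. A background near 81.69 units stays in both values of a gene, and differences of dim genes are therefore understated.

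In place of the detection p-values, a background floor was set from the values. The background mode was 81.69 units, the middle of the shortest interval holding 25% of all values, and the SD of the values below it was 2.56. The floor was the mode plus 4 SD, or 91.92 units, a multiple chosen after these values and some of the unassigned detection p-values had been seen. Probes at or above it numbered 16809 on the control array and 16794 on the CA/CA array. Of the 45281 probes, 34885 were paired with 1 gene symbol by the platform annotation, 18 with several and 10378 with none, and only the first kind was given a gene name. Of the named probes, 34807 had an Entrez identifier in the RefSeq gene table of assembly GRCm38.p6, and no symbol needed updating. No coordinates are given because the array files name no genome build.

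Probes of 1 gene were averaged over those above the floor on at least 1 array. Signals are means over these probes, and the log2 difference, CA/CA minus control, is the mean of the probe differences. Of 19057 genes on the array, 10140 were above the floor on at least 1 array and 8516 on both. For a gene above the floor on 1 array only, the difference is given as an at-least fold against the higher of the lowest signal above the floor, 91.92, and the gene's own dim signal. With 1 array per group there is no replicate error, no test and no p-value for any gene, and the 2 arrays stand for 2 samples, not for 2 genotypes in general. The number of arrays limits the precision. The spread between different probes of 1 gene, an SD of 0.24 on the log2 scale over 3868 genes with 2 or more probes, measures probe error only.

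Before the data were examined, 25 gene lists, the size rule of a 2-fold difference and the rule for named genes were fixed. The rule takes the 12 largest differences in each direction among genes above the floor on both arrays, up to 5 genes per direction above the floor on 1 array only, up to 5 members of each list with the largest difference, Ikbkb and the sex-linked genes. For each list the median difference is given over its measured members, those above the floor on at least 1 array. Beside it stand an exact binomial order-statistic 95% interval over genes, which are not replicates, and the central 95% of the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. This places a list within these 2 arrays and is not a test of genotype. Every list's result is plotted or given, and list medians are not independent where lists share genes.

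The steps were tested on simulated data. In a simulated control against CA/CA pair of 9115 genes with an assumed noise level, 79 of 100 genes changed 4-fold in their signal above background passed the 2-fold rule, and 0 unchanged genes did. Both simulated arrays were drawn from the control array, with noise set below the spread between probes of 1 gene. The changed genes had control signals well above background, and no variation between mice, sorts or RNA preparations was simulated. The counts therefore check the steps and give no error rate for the real arrays. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The alternatives were normexp background correction of the deposited values with limma 3.58.1 in R 4.3.3, no offset, an offset of 50, other floors, no floor, floored dim signals, the brightest probe per gene and other fold thresholds.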

Results

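The transcriptomes of 2 samples of mouse hematopoietic stem and progenitor cells were profiled on Illumina bead arrays. Both samples were sorted as Flt3-low LSK cells, the lineage-negative, Sca1-positive, c-Kit-positive fraction that holds the hematopoietic stem cells (HSCs). One sample was a control and the other carried the genotype written CA/CA, read here as that of the transgenic mice of the series, whose HSCs express a constitutively active form of IKK2. IKK2, encoded by Ikbkb, is a kinase that activates the canonical NF-kB pathway. The comparison asks how gene expression in these cells differs when IKK2 is permanently active. Each genotype had 1 array, so no value has a replicate error and no difference was tested. How many mice gave each sample is not given in the sources used here. Both arrays carried 45281 probes, and 37.1% of the probes on each were above the background floor of 91.92 signal units.

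The measured signal of Ikbkb itself was alike in both samples. The 1 Ikbkb probe above the floor, ILMN_2589556, had a signal of 205 in both the control and the CA/CA sample, and the other 2 lay below the floor on both arrays. The labels do not say which sequence the transgene carries, so these probes do not check it. Among sex-linked genes, Xist, the RNA of the inactive X chromosome, had a signal of 189 in the control and 116 in CA/CA, and all 4 of its probes were lower in CA/CA. Of the Y-linked genes, 1 of 2 Eif2s3y probes was above the floor, at 147 in the control and 209 in CA/CA, and 1 of 4 Uty probes, below the floor in the control and at 103 in CA/CA. All other probes of these genes, and both Kdm5d probes, were below the floor on both arrays. Eif2s3x, the X-linked relative of Eif2s3y, was at 476 in the control and 808 in CA/CA. Whether the Eif2s3y probe also binds it was not checked. The sex-linked list had a median of 0.19 over 3 measured genes. The sex of the mice is not given in the sources used here.

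Of 8516 genes above the floor on both arrays, 111 were at least 2-fold higher and 159 at least 2-fold lower in CA/CA. After normexp background subtraction the counts were 231 and 398, and at a 3-fold threshold the higher genes were the larger group, 41 against 31. The median difference over all 8516 genes was 0.01 on the log2 scale, with a central 95% range from -0.89 to 0.74. A further 832 genes were above the floor only in the control and 792 only in CA/CA. Among 398 genes whose brightest probe differed at least 2-fold, 181 had another probe above the floor on at least 1 array. Of these 259 other probes, 247 differed in the same direction. Of the 25 gene lists, 7 had a median above and 8 a median below the central 95% of matched random lists.

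**Figure D1:**
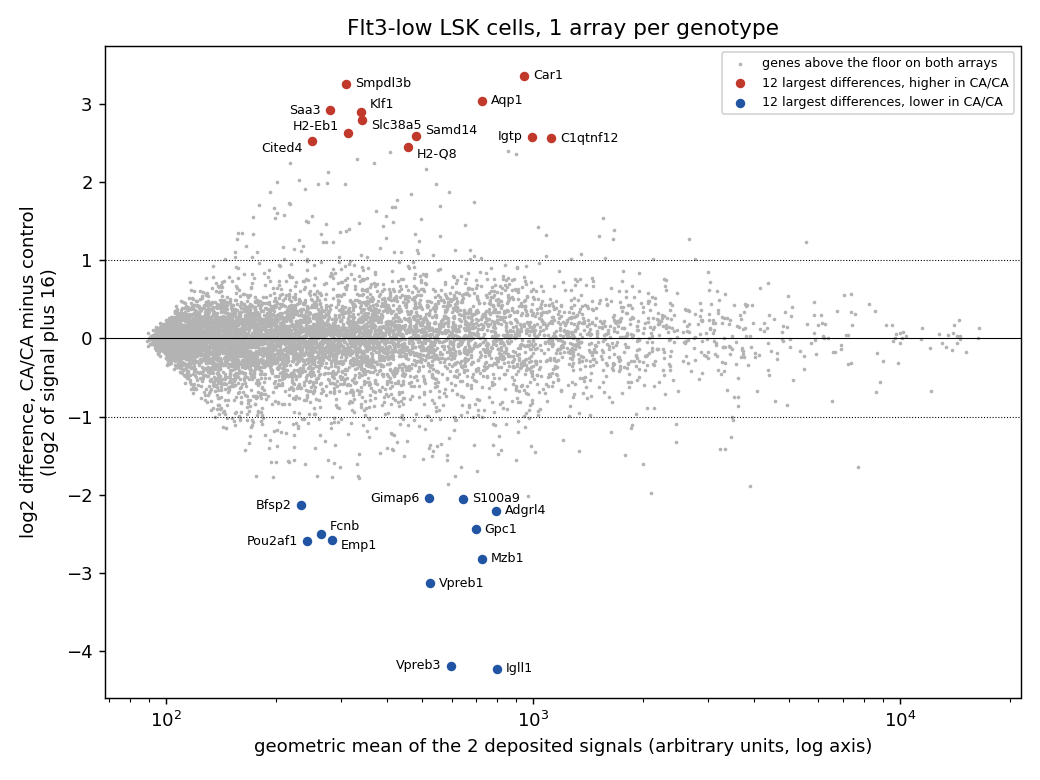
Each point is a gene above the background floor on both arrays, with the geometric mean of its signals on a log x axis (arbitrary units) and its log2 difference, CA/CA minus control, on the y axis. Dotted lines mark 2-fold differences, and the 12 largest differences in each direction are coloured and named, from Car1 at 3.36 to Igll1 at -4.22.

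Erythroid genes had the list median farthest from 0 and were on balance higher in CA/CA. Car1, a carbonic anhydrase of early red cells, had a signal of 289 in the control and 3112 in CA/CA, a log2 difference of 3.36. Aqp1, the red cell water channel, was at 240 and 2198, with all 3 probes higher by 2.68 to 3.24. Klf1, the master transcription factor of erythroid differentiation, was at 118 and 978. Blvrb, a biliverdin reductase, was at 342 and 2142, and Ermap, an erythroid membrane protein, was below the floor in the control and at least 4.65-fold higher in CA/CA. Of 19 measured members, 13 were at least 2-fold higher, 1 was at least 2-fold lower and 5 lay within 2-fold. The list median was 1.38 (95% interval over genes 0.16 to 2.29), against -0.17 to 0.17 for matched random lists. Chosen after their values were seen, Gata1 and Epor, the erythroid transcription factor and the erythropoietin receptor, differed by 1.02 and 1.57, while the alpha-globin gene Hba-a1 had a signal of 1036 in the control and 939 in CA/CA, and Nfe2 was the member at least 2-fold lower, at -1.15. Other genes among the 12 largest positive differences, outside this list, were Slc38a5, an amino acid transporter (123 and 947), Samd14 (189 and 1218), Cited4 (98.21 and 638), C1qtnf12 (455 and 2756) and Smpdl3b (93.31 and 1027). Another Samd14 probe, ILMN_1235581, was below the floor on both arrays.

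Genes of B cell progenitors were lower in CA/CA and held the largest differences among genes above the floor on both arrays. Igll1 and Vpreb1, which form the surrogate light chain of the pre-B cell receptor, had signals of 3589 and 1611 in the control and 177 and 170 in CA/CA, log2 differences of -4.22 and -3.13. Vpreb1 has a near-identical paralogue, Vpreb2, and the array may not separate them. Vpreb3 was at 2690 and 133, a difference of -4.19. Cd79b, a B cell receptor component, was at 1174 and 321, and Blnk, an adaptor of that receptor, was at 328 in the control and below the floor in CA/CA, at least 3.12-fold lower. Mzb1 and Pou2af1, genes of the B cell lineage, differed by -2.82 and -2.60. Of 19 measured lymphoid priming genes, 0 were at least 2-fold higher and 6 at least 2-fold lower, with a median of -0.63 (95% interval -1.70 to -0.10) against -0.15 to 0.15 for random lists. It was -1.03 after normexp subtraction and -0.17 with all probes kept, against -0.05 to 0.05.

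Genes of granulocytes and monocytes were on balance lower in CA/CA. Fcnb, a secreted ficolin, was at 670 in the control and 104 in CA/CA. The calprotectin subunits S100a8 and S100a9 were at 7503 and 1337 in the control and at 2020 and 310 in CA/CA. Elane, neutrophil elastase, was at 13646 and 4340, a log2 difference of -1.65. Lcn2, the secreted iron-siderophore binder lipocalin 2, was higher in CA/CA, at 305 and 1020. Of 36 measured members 2 were at least 2-fold higher and 7 at least 2-fold lower, with a median of -0.20 (95% interval -0.33 to -0.03) against -0.10 to 0.11 for random lists. Besides Lcn2, the other member at least 2-fold higher was Hp, at 1778 and 3973. Above 0 were 11 members and below 0 were 25. The megakaryocyte list had a median of -0.10, inside its random range, and of -0.06 with all probes kept, there below its random range of -0.05 to 0.05, with Gp9 and Cd9 at -1.37 and -0.89 and F2r, a thrombin receptor, at 0.70.

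Interferon-stimulated genes and antigen presentation genes were on balance higher in CA/CA. The interferon-inducible GTPase genes Igtp, Gbp2, Gbp3 and Ifi47 differed by 2.57, 2.35, 1.74 and 1.77 on the log2 scale, with Igtp at a signal of 400 in the control and 2465 in CA/CA. Cxcl9, a chemokine induced by interferon gamma, was below the floor in the control and at least 3.93-fold higher in CA/CA. Of 32 measured interferon-stimulated genes, 7 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 0.37 (95% interval 0.06 to 0.90) against -0.11 to 0.11 for random lists. With all probes kept whatever their signal the median was 0.09. Chosen after their values were seen, genes known to be induced by type I interferon lay on both sides of 0, with Isg15 at 1.57, Usp18 at 1.01 and Oasl2 at 0.51 and Ifit3 at -0.21 and Rsad2 at -0.42.

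Among antigen presentation genes, the MHC class II genes H2-Eb1 and H2-Ab1 were at signals of 120 and 302 in the control and 817 and 1153 in CA/CA. Cd74, the class II invariant chain, was at 205 and 1056, with its 3 probes higher by 0.63 to 2.45, and Tapbp, the class I loading factor tapasin, was at 143 and 368. H2-Aa was below the floor in the control and at least 1.86-fold higher in CA/CA. The class I-like gene H2-Q8 differed by 2.45, and its probes may also bind close relatives in the H2-Q family. All 20 genes on the list were measured, 4 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 0.59 (95% interval 0.13 to 0.86) against -0.15 to 0.15 for random lists. Above 0 were 17 members. The 3 below 0 were the class II genes H2-DMa and H2-DMb1, at -0.35 and -0.27, and Cd86, at -0.47, so class II genes differed in both directions.

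**Figure D2:**
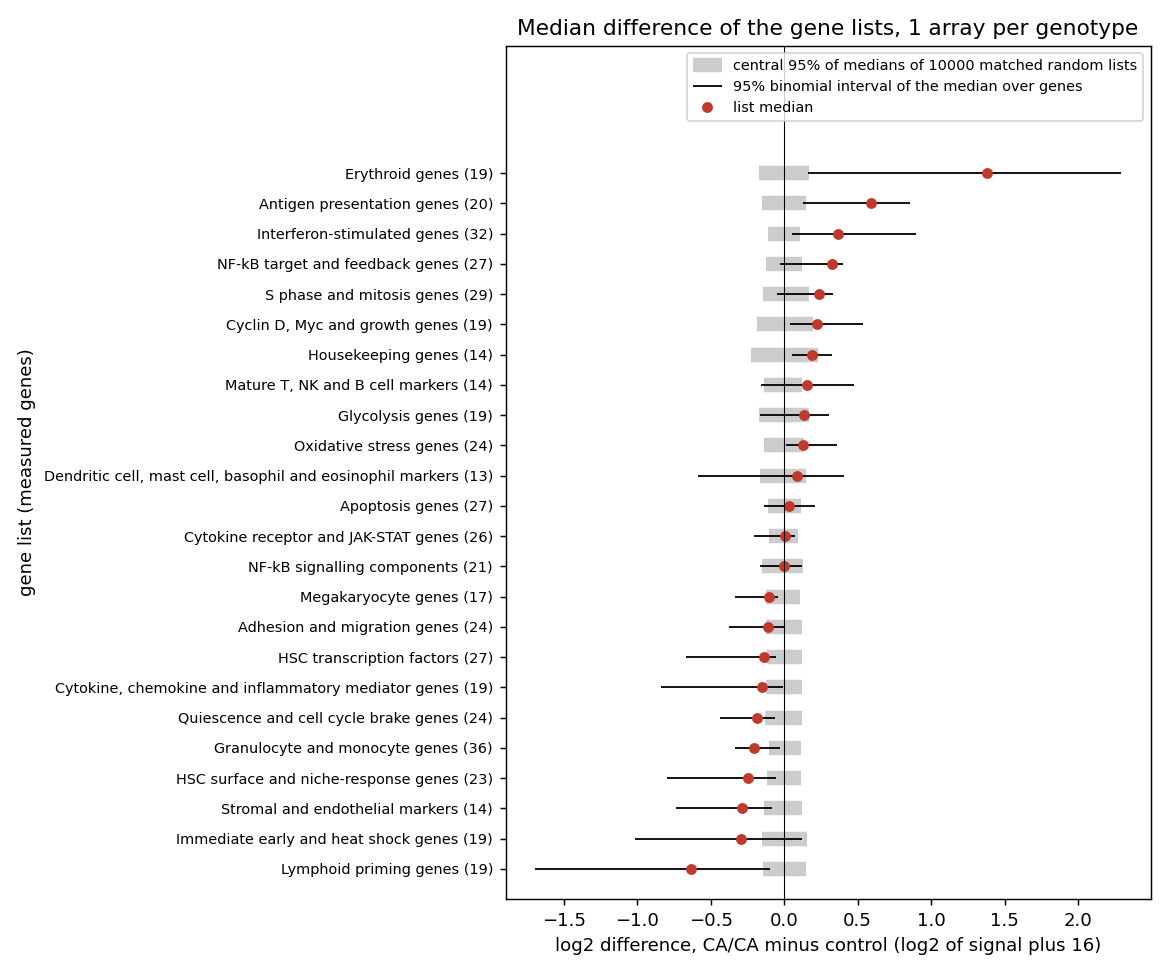
Each line is a gene list that has an interval, which leaves out the sex-linked list, with its number of measured genes, and the x axis is the log2 difference, CA/CA minus control. Red points are list medians, black lines 95% binomial intervals over genes and grey bars the central 95% of matched random lists; erythroid genes lie farthest above 0, at 1.38, and lymphoid priming genes farthest below, at -0.63, while the medians of NF-kB signalling components, cytokine receptor and glycolysis genes changed sign in some settings.

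NF-kB target and feedback genes were on balance higher in CA/CA, by less than the erythroid list. Tnfaip2, a gene induced by tumour necrosis factor, was at 204 in the control and 686 in CA/CA, with all 3 probes higher. Relb, an NF-kB subunit, was at 105 and 258. Sod2, mitochondrial superoxide dismutase, was at 1092 and 2251. Nfkbia, the NF-kB inhibitor that NF-kB itself induces, differed by 0.92, and its 2 probes by 0.20 and 1.64. Cxcl10, a chemokine also induced by interferon, was below the floor in the control and at least 3.29-fold higher in CA/CA. Of 27 measured members, 4 were at least 2-fold higher, 0 at least 2-fold lower and 23 within 2-fold, with a median of 0.33 against -0.12 to 0.12 for random lists. Above 0 were 19 members and below 0 were 8, with Ltb the lowest, at 425 in the control and 272 in CA/CA, a difference of -0.62. The 95% interval over genes, -0.03 to 0.40, included 0. The median was 0.60 after normexp subtraction and 0.06 with all probes kept whatever their signal. The list of NF-kB signalling components had a median of 0.00, of either sign across settings, and 0 of 21 members beyond 2-fold. In it, Tlr2 and Myd88, a receptor and an adaptor upstream of NF-kB, differed by 0.77 and 0.58, and Map3k14, the kinase of the non-canonical pathway, by -0.66.

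The list of cytokine, chemokine and inflammatory mediator genes did not share that direction. The chemokines Cxcl9, Cxcl10 and Ccl5, higher in CA/CA, stood in other lists and are not counted in this one. Saa3, an acute-phase serum amyloid, was at 94.94 in the control and 820 in CA/CA, while Il15 and Il12a differed by -1.24 and -1.15 on the log2 scale. The list median was -0.15 (95% interval -0.84 to -0.01), with 1 of 19 members at least 2-fold higher and 4 at least 2-fold lower, S100a8 and S100a9 among them. It was -0.49 after normexp subtraction and -0.01 with all probes kept, there inside its random range of -0.03 to 0.03. In the cytokine receptor and JAK-STAT list the median was 0.01, of either sign across settings, and the mean -0.08, and Stat4 was the 1 member beyond 2-fold, at -1.03.

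Genes of the HSC state were on balance lower in CA/CA. Robo4 and Esam, surface proteins of HSCs and endothelium, were at 595 and 439 in the control and below the floor in CA/CA, at least 5.66-fold and 4.21-fold lower. Cd93 and Ltb4r1 differed by -1.55 each. Thy1 was the member at least 2-fold higher, at 232 and 657. Of 23 measured HSC surface and niche-response genes, 5 were at least 2-fold lower and 1 higher, with a median of -0.25 (95% interval -0.79 to -0.05) against -0.12 to 0.11 for random lists. With all probes kept it was -0.09, against -0.05 to 0.05. Of the 23 members, 17 lay within 2-fold. Procr, Kit and Eng, chosen after their values were seen, were among these, at 0.02, -0.18 and -0.08. Among HSC transcription factors, Meis1 was at 539 in the control and 153 in CA/CA, Hoxa5 at 270 and 122, and Gfi1 at 892 and 425. Nkx2-3 differed by -1.02, with its 2 probes at -1.79 and -0.24. Gfi1b, which also acts in erythroid and megakaryocytic differentiation, was higher, at 195 and 577. Of 27 measured factors, 4 were at least 2-fold lower and 1 higher, with a median of -0.14 (95% interval -0.67 to -0.06) against -0.12 to 0.12 for random lists. It was -0.42 after normexp subtraction and -0.09 with all probes kept, against -0.05 to 0.05. Within 2-fold lay 22 of the 27. Runx1, Prdm16 and Hoxb4, chosen after their values were seen, were among these, at 0.00, -0.06 and -0.06. Stromal and endothelial markers, of which HSCs share some, had a median of -0.29 (-0.08 with all probes kept), with 12 of 14 members below 0. Emcn, an endothelial and HSC surface mucin, was at least 3.01-fold lower. Sparc and Cxcl12 were below the floor in CA/CA, at least 1.62-fold and 1.61-fold lower, and Igfbp4 was at -0.74. Col5a1 was higher, at 106 and 369. Which cells carried the genes shared by HSCs and endothelium cannot be told from these arrays.

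Quiescence and cell cycle brake genes were on balance lower in CA/CA. Cdkn1c, the cyclin-dependent kinase inhibitor p57, was at 350 in the control and 107 in CA/CA. Txnip, a thioredoxin inhibitor, was at 2186 and 811, Egr1 at 433 and 199, and Foxo1 at 210 and 99.85. Ndn, the growth suppressor necdin, was below the floor in CA/CA and at least 2.31-fold lower. Of 24 measured members, 0 were at least 2-fold higher and 4 at least 2-fold lower, with a median of -0.19 (95% interval -0.44 to -0.06) against -0.13 to 0.12 for random lists. This median was -0.10 with all probes kept, against -0.05 to 0.06. S phase and mitosis genes had a median of 0.24 (95% interval -0.05 to 0.33) against -0.14 to 0.17, but 0 of 29 differed 2-fold. With all probes kept the median was 0.06, inside its random range of -0.07 to 0.08. In that list the cyclins Ccne1 and Ccne2 were at 0.94 and 0.78 and Cdk1 was at -0.45. In the list of cyclin D, Myc and growth genes, with a median of 0.22 (95% interval 0.04 to 0.53) against -0.18 to 0.20 for random lists and of 0.41 after normexp subtraction, Odc1, the rate-limiting enzyme of polyamine synthesis, was at 1484 and 3022, and Ddx21 and Nop56, which act in ribosome assembly, were at 0.75 and 0.66.

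**Figure D3:**
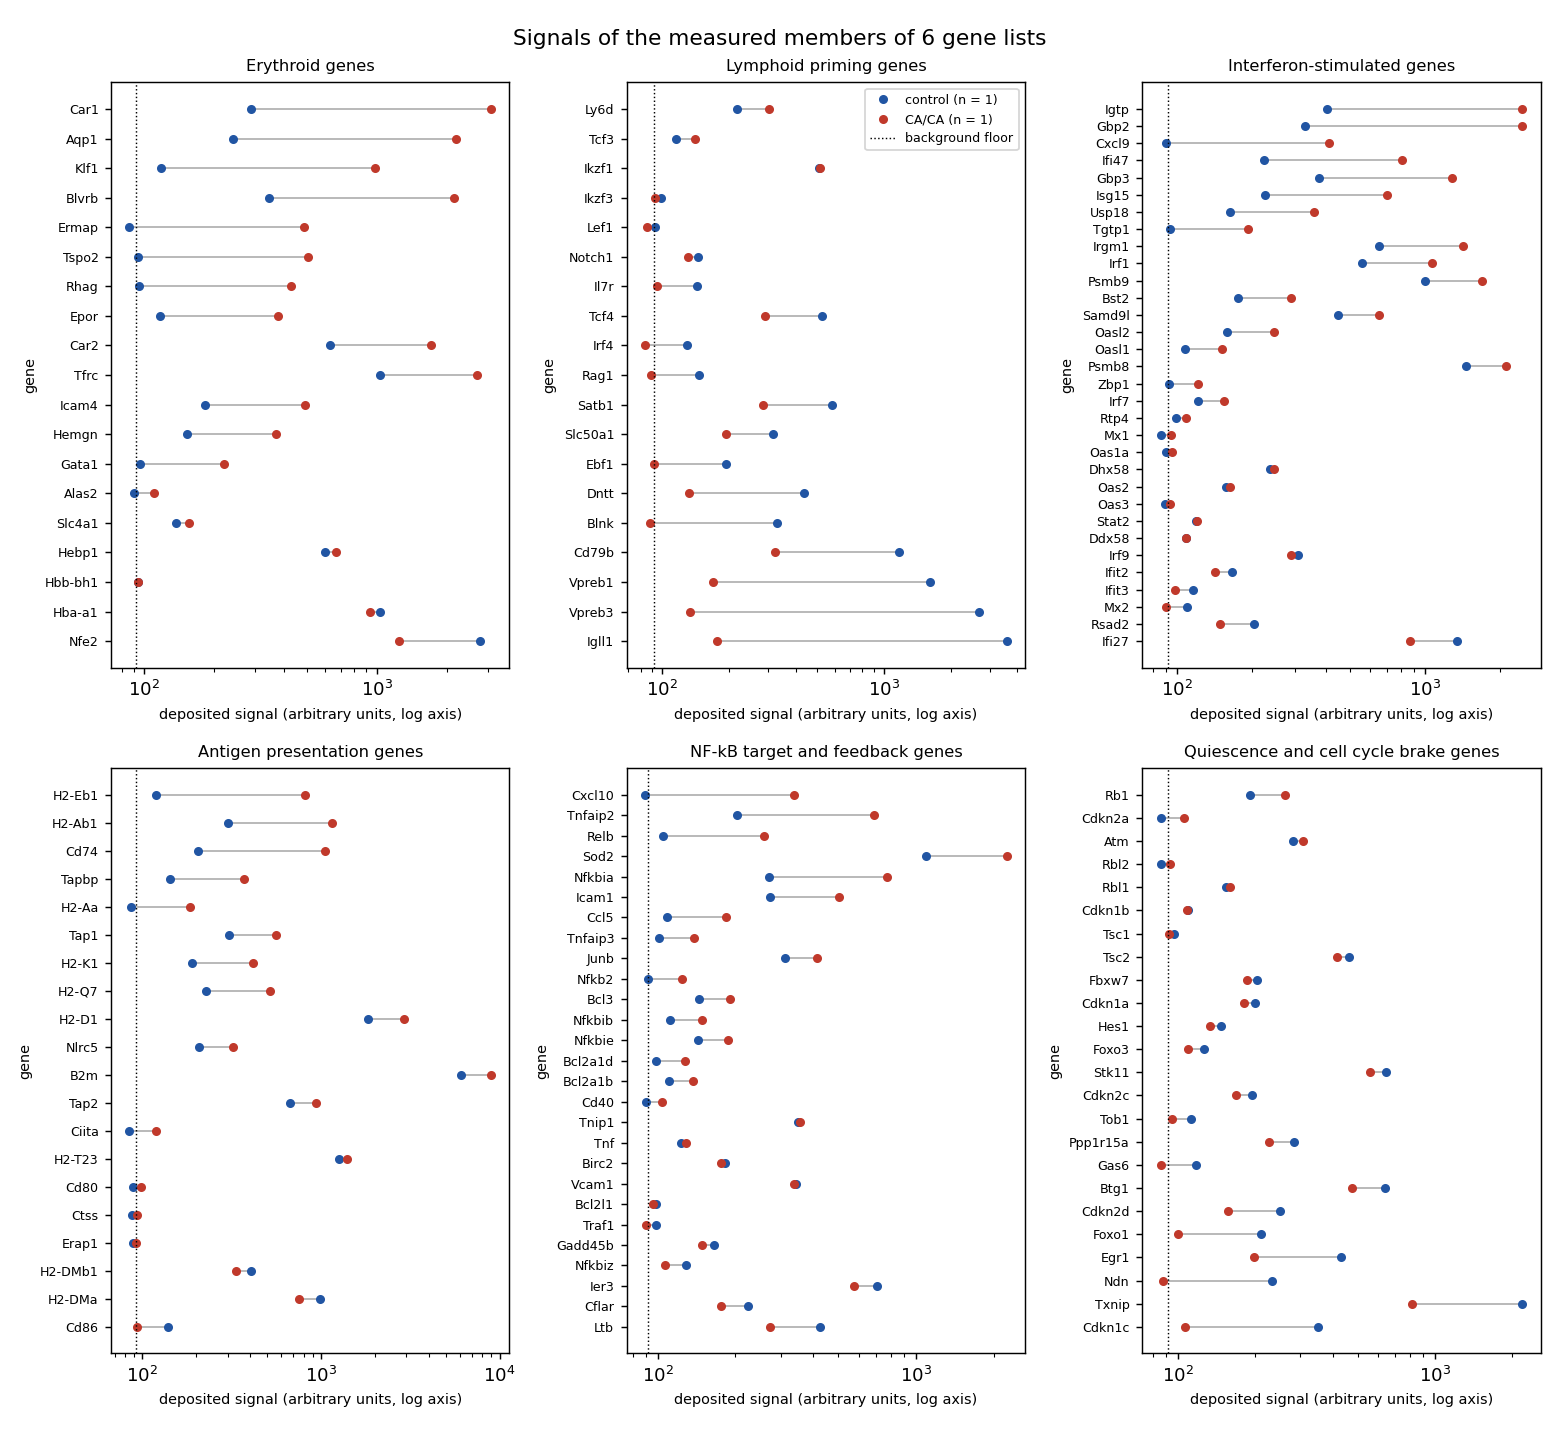
Each panel shows the measured genes of 1 list, with the deposited signal on a log x axis (arbitrary units), the control sample in blue, the CA/CA sample in red and the background floor of 91.92 as a dotted line (1 array each). Most erythroid and antigen presentation genes lie to the right in CA/CA, most lymphoid and quiescence genes to the left.

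Immediate early genes were mostly lower in CA/CA, with Junb higher at 0.39, while heat shock genes on the same list were mostly higher. Dusp2, Fos, Zfp36, Egr1 and Dusp1 differed by -1.50, -1.41, -1.40, -1.06 and -1.01, and these 5 were the members at least 2-fold lower. The list median was -0.29, with a 95% interval from -1.01 to 0.12, against -0.15 to 0.15 for random lists. It was -0.67 after normexp subtraction and -0.14 with all probes kept. Chosen after their values were seen, the heat shock genes Hsph1, Hsp90aa1 and Hspa8 were at 0.73, 0.37 and 0.29 and Dnajb1 at -0.26. Egr1 is counted in the quiescence list as well. Oxidative stress genes had a median of 0.13, inside their random range, and of 0.09 with all probes kept, there above their random range of -0.06 to 0.07, with Gclm, which supports glutathione synthesis, at 243 and 709 and Gpx3 at -0.86. The medians of the apoptosis, glycolysis and adhesion lists were 0.03, 0.13 and -0.11 and lay inside their random ranges, and the glycolysis median was -0.01 with all probes kept. Among their members, Casp1 was at 0.67, Hk3 at -1.25 and Vav1 at -0.77.

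Markers of mature cells that a sort could carry along differed in both directions. In the list of mature T, NK and B cell markers, Nkg7, a cytotoxic granule gene, was at 4190 in the control and 1055 in CA/CA, while Cd3d was at 102 and 154 and Cd6 at 100.3 and 146. Prf1 and Klrd1, chosen after their values were seen, were dim, at 163 and 147 and at 91.38 and 116, and did not share the Nkg7 level. Of 14 measured members, 9 were above 0 and 0 at least 2-fold higher. The list median was 0.15 (95% interval -0.15 to 0.47), above the -0.14 to 0.12 of random lists. It was 0.61 after normexp subtraction and 0.02 with all probes kept, there inside its random range of -0.04 to 0.04. Among markers of dendritic cells, mast cells, basophils and eosinophils, Hdc and Prss34 were lower, at -1.45 and -1.10, while Mcpt4 and Tpsb2 were below the floor in the control and at least 1.43-fold and 1.33-fold higher in CA/CA. Of 13 measured members 9 were above 0, and the list median of 0.09 and mean of -0.07 differed in sign. Housekeeping genes had a median of 0.19 (95% interval 0.05 to 0.33), inside the -0.23 to 0.23 of random lists, with 13 of 14 members above 0. Among them, Tfrc, the transferrin receptor that also counts as erythroid, was at 1.38 and Actb at 0.64. The 5 probes of Actb differed in direction and ran from -0.04 to 1.90.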

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

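No replicate could be left out. No paired analysis was possible because each genotype had 1 array and the labels give no replicate numbers. Uncorrected signals and detection p-values of the non-normalized table, foreseen as alternatives, were not run because its headings match no label and columns were not assigned by their values, and the offset of 50 was added to the deposited values. Normexp subtraction without median scaling, the floors of 3 SD and 6 SD and dim signals set to the floor were chosen after seeing the data. Normexp subtraction, which takes the common background out of both values of a gene, gave 231 genes at least 2-fold higher and 398 lower (397 with median scaling) against 111 and 159. With it 5 list medians left their 95% interval, each farther from 0: NF-kB targets 0.60, megakaryocyte genes -0.36, mature T, NK and B cell markers 0.61 (0.62 with median scaling), stromal and endothelial markers -0.75 and antigen presentation genes 0.91. The sex-linked median, which has no interval, was 0.57. With all probes kept, which adds genes at background, the stromal and endothelial median was -0.0789 (main interval -0.74 to -0.08). A 1.5-fold threshold gave 369 higher and 536 lower genes and a 3-fold threshold 41 and 31. Over the 9 alternatives the erythroid median ran from 1.02 to 1.81, the lymphoid one from -1.03 to -0.17, the interferon one from 0.09 to 0.60, the NF-kB target one from 0.06 to 0.60 the quiescence one from -0.28 to -0.10, the HSC transcription factor one from -0.42 to -0.09, the HSC surface one from -0.49 to -0.09, the S phase and mitosis one from 0.06 to 0.25, the mature T, NK and B cell one from 0.02 to 0.62 and the cytokine and mediator one from -0.49 to -0.01. It ran from -0.67 to -0.14 for immediate early and heat shock genes, 0.20 to 0.41 for cyclin D, Myc and growth genes, -0.30 to -0.15 for granulocyte and monocyte genes, -0.36 to -0.06 for megakaryocyte genes, 0.03 to 0.25 for dendritic cell, mast cell, basophil and eosinophil markers, 0.52 to 0.91 for antigen presentation genes, 0.09 to 0.17 for oxidative stress genes, 0.00 to 0.06 for apoptosis genes, -0.17 to -0.03 for adhesion genes, 0.02 to 0.57 for sex-linked genes and 0.14 to 0.20 for housekeeping genes. With all probes kept, and random lists drawn in that setting, 6 list medians lay above and 8 below their random range (7 and 8 with the floor). S phase and mitosis, mature T, NK and B cell and cytokine and mediator genes then lay inside it, oxidative stress genes above it (0.09 against -0.06 to 0.07) and megakaryocyte genes below it (-0.06 against -0.05 to 0.05). Medians changed sign in 3 of the 9 for NF-kB signalling components (-0.02 to 0.01) and for cytokine receptor genes (-0.11 to 0.03) and in 1 for glycolysis genes (-0.01 to 0.20), and kept it in the other lists. Of the 137 named genes, 95 moved by more than 0.24 under normexp subtraction, and 0 of those with a 2-fold difference changed direction in any alternative. Signal near background limits what can be seen of dim genes.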

Other observations

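The gene families, the test of a lower share of 1 main cell type and the test of mature B cells were chosen only after the values they use were seen. Families of related genes, taken by symbol, added further differences. All 6 measured Gimap genes, which encode small GTPases of lymphocytes, were lower in CA/CA, with a median of -1.04. Gimap6 was at 1083 in the control and 250.3 in CA/CA, Gimap1 at 915 and 216 and Gimap8 at 361 and 111. All 5 measured guanylate-binding protein genes were higher, with Gbp5 at 96.24 and 255 and Gbp7 at 147 and 368. All 16 measured tRNA synthetase genes with symbols of the form Aars were above 0, none by 2-fold, with a median of 0.38 against -0.17 to 0.18 for matched random lists. Among them, the dim Cars, Hars, Tars and Yars were at only 0.02, 0.05, 0.09 and 0.11, less than the SD of 0.24 between probes of 1 gene. Wars, which interferon induces, and Aars were at 0.94 and 0.90. Of 39 genes with Psm symbols, mostly proteasome subunits, 35 were higher, with a median of 0.28. Of 43 genes with Eif symbols, mostly translation initiation factors but also their kinases and binding proteins, 33 were higher, with a median of 0.25. The 53 genes with Rpl and Rps symbols, mostly ribosomal proteins, had a median of -0.01, and the 42 with Nduf symbols, complex I subunits and assembly factors, one of 0.07, both inside their random ranges. Of 12 families examined, the H2-Q median was 0.76 and that of Tspan -0.16, while Hox, Cox and Serpin, at -0.05, 0.09 and 0.02, lay inside their random ranges. The Serpin median changed sign in 1 of 9 alternative settings and the other families kept theirs. Among genes above the floor on 1 array only, Ehd3, Fpr2 and Gpat2 were at least 5.33-fold, 5.23-fold and 4.62-fold higher in CA/CA, and Fxyd6 was at least 2.88-fold lower. Among the largest differences, Emp1, Gpc1, Adgrl4 and Bfsp2 were lower in CA/CA, at -2.58, -2.44, -2.21 and -2.14. Of 2015 probes without a gene name that were above the floor on both arrays, 17 were at least 2-fold higher and 42 at least 2-fold lower.

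Noise of single probes as the source of the 2-fold differences is argued against for genes with another probe above the floor on at least 1 array. Of these other probes, 95.4% differed in the same direction (247 of 259, Wilson 95% interval 92.1% to 97.3%), where noise would give about 50%. Only 181 of the 398 genes had such a probe, and Igll1, Vpreb3, Car1 and Klf1 were not among them. Probes below the floor on both arrays were not counted, so they could not lower the share. The agreement says nothing of differences between mice, sorts or RNA preparations, which cannot be told apart from genotype with 1 array per genotype.

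For the pattern of higher erythroid and lower B cell progenitor genes in CA/CA, a lower share of 1 main cell type was considered. It would leave the genes of all other types higher alike. The intervals of lymphoid priming genes (-1.70 to -0.10) and of granulocyte and monocyte genes (upper bound -0.0289) both lay below 0. These values argue against a main type that carries only 1 of these lists or neither. A lower share of a main type that carries both stays open. The megakaryocyte list does not decide this, as its median lay inside its random range and most of its signals were near the floor. A candidate explanation is that the sorted gates held different progenitors, with erythroid progenitors in or at the edge of the CA/CA gate. A list of 17 measured haem synthesis and red cell membrane genes, fixed before its values were seen, had a median of 0.74 against -0.16 to 0.14 for random lists (0.50 against -0.09 to 0.09 with all probes kept), with 11 of the 17 above the floor in the control and Alad at 907 and 2668. In the erythroid list, the abundant globin transcript Hba-a1 was not higher, at 1036 and 939, and the dim Alas2 and Slc4a1 differed by only 0.24 and 0.16. Klf1, Car1 and Epor of that list were higher, by 2.89, 3.36 and 1.57, so Hba-a1 alone does not decide the question. B cell progenitors in the control gate also remain possible, as 15 further B cell progenitor genes, all above the floor in the control and 1 of them in an earlier list, had a median of -0.36 against -0.16 to 0.17 (-0.16 against -0.08 to 0.08 with all probes kept), with Hmgn3 at 580 and 195 and Cd72 at 314 and 118. Either source would need cells that passed the lineage-negative, Sca1-positive, c-Kit-positive and Flt3-low gates or sat at their edge, which these arrays cannot check. A shift of expression within the same cells, which the genotype may bring, stays open and untested.

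The higher interferon-stimulated and antigen presentation genes in CA/CA could come from macrophages in the sort, which a lineage-negative gate would mostly remove, but 15 measured macrophage genes, with 3 listed genes also in an earlier list, had a median of -0.48 against -0.15 to 0.14 for random lists (-0.16 against -0.05 to 0.05 with all probes kept). The abundant Psap was at 2662 and 1725, Ctsb at 964 and 1044 and Apoe at 374 and 133. A small share of mature B cells, which carry MHC class II and which a lineage-negative gate would also mostly remove, stays open: Cd79b was lower in CA/CA, at -1.76, but its control signal of 1174 can hide one, Tnfrsf13c and Ly6d were higher, at 0.35 and 0.43, Cd72 and the dim Fcmr lower, at -1.30 and -0.50, and all probes of Ms4a1, Cd22, Cr2 and Fcer2a were below the floor on both arrays. With normexp subtraction the antigen presentation median was 0.91, of the same sign. An effect of the genotype, of a different sex composition of the samples, which the Xist and Eif2s3y signals leave possible, or of the state of the mice remains open and untested.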
